A study of Homo sapiens with 6 samples.

How the data were processed

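The series holds 6 RNA-seq libraries of MCF-7 cells grown in medium with 10% serum and then kept for 72 h on collagen that had polymerised for 4 h, with or without collagen-tracks. Libraries were made with a stranded Illumina mRNA ligation kit, per the labels' protocols. The values are raw counts per Ensembl gene as deposited by the authors, with no normalization, in 1 table with a column per library. Trim Galore, cutadapt, FastQC, STAR and DESeq2 and the build hg38 are named in the submitters' processing notes, without versions or roles. The counting tool, its strand setting and the annotation release are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping gene on the other strand cannot be told apart. This touches VIM, ZEB1, PLAU, DPYD, IGFBP7, COL4A1, COL4A2, LOX, MYL9, ITGA6, ITGB3, SH3PXD2A, EGR3, SATB1, YOD1, IGF2BP3, CDH1, ESR1, CTTN, ITGB1, PDCD4, PTEN, CLTC and FDFT1, besides the lower genes named below as uncertain. ETV5, SATB1, CDH1 and PTEN overlap a tested gene on their own strand.

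Columns were assigned to samples through the library codes in the labels, and groups and replicate numbers were taken from the sample titles. The table held 60669 genes, of which 25734 had no count in any library. Symbols came from a table of gene names that held 99.5% of the IDs. Coordinates of the genes named are those of GENCODE release 29 on hg38, which held 98.4% of the genes tested. Totals ranged from 77458588 to 140791812 counts, so that 3 counts, taken as the floor of detection, correspond to 0.0213 to 0.0387 CPM. The replicates of a group differed by far more than counting noise, with a chi-square per gene of 11.2 to 141, and were kept as separate samples.

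The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, edgeR 4.0.16 in R 4.3.3) with TMM factors of 0.975 to 1.04, edgeR's default filter on low counts by group, and Benjamini-Hochberg adjustment over 19657 genes at a threshold of 0.05. CPM values use the TMM-scaled totals. A fold change is given on the log2 scale with its standard error, computed here from the deposited counts. A ratio of summed counts with an exact binomial 95% interval is given where the collagen group had 1 to 3 counts. The 35 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), with camera using an estimated correlation, and with fry. Of these lists 20 passed camera, 18 upwards and 2 downwards, none with an estimated correlation, 13 passed fry's test of a movement one way and 21 its test in either direction. Of the listed genes, 44 were not among those tested. Bootstrap intervals of medians used 2000 resamples. Figures were drawn with matplotlib 3.10.9.

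The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Named were the 12 genes with the largest change in each direction among called genes with a symbol, at least 2 CPM in the higher group and no overlap between groups, the 5 genes with the smallest adjusted p in each direction, up to 4 called members of each list or otherwise the 2 with the smallest p, and a fixed set of genes on adhesion, invasion and microRNA targets. IGFBP6 was named after its values were seen.

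Replicate numbers are shared by the groups, per the sample titles. The deviations of same-numbered libraries from their group means correlated across genes with r = 0.287 for number 1, 0.294 for number 2 and 0.451 for number 4, each over the limit of 0.1 set in advance, so the numbers were taken to pair the libraries. Genes are not independent replicates. The main test was planned without the number, so shared deviations of same-numbered libraries stay in its error. The fit with the number as a replicate block is an alternative, given beside a result where it changes it. The other alternatives were DESeq2's size factors, library totals alone, no filter on low counts, filters at 1 CPM in 3 libraries and at 10 CPM on average, DESeq2 1.42.0, limma-voom, edgeR's older quasi-likelihood form, a test against a fold of 1.5, and fits without each library or each replicate number.

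The tests were tried on simulated counts with the means, dispersions and totals of this comparison, in which 200 of 19657 genes were changed. edgeR recovered 25.0% of genes at a log2 fold of 0.5, 62.1% at 1 and 97.0% at 3, and 8.96% of its calls were false. In the same simulation, which held no pairing, false calls were 13.3% with the replicate block and 31.7% with DESeq2. Of 200 lists left unmoved, camera gave an unadjusted p under 0.05 for 4%.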

Results

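Polyadenylated RNA was sequenced from MCF-7 cells, an established luminal breast cancer line of epithelial type that carries the estrogen receptor. The cells were kept for 72 h on a collagen matrix of 0.5 mg/ml, either plain or decorated with collagen-tracks. The labels do not name the cells that left the tracks. Each group held 3 libraries, numbered 1, 2 and 4. The libraries on collagen held 111698814, 119716599 and 119848250 counts, and those with collagen-tracks held 140791812, 77458588 and 86907908. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The series title asks whether tracks left by cancer cells pass on invasive properties through the microRNAs they hold. The comparison of both groups covers gene expression only. Neither invasion nor microRNAs were measured in these libraries, so it cannot show that a change passes through microRNAs.

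With collagen-tracks, genes of a mesenchymal and matrix-remodelling kind rose from low or undetected levels, while the epithelial and luminal genes of MCF-7 cells did not pass the main test. That test recovered 25% of simulated genes at a log2 fold of 0.5, so modest falls are not excluded. No sample held tracks without MCF-7 cells, so a rise may come from these cells or from other RNA carried with the tracks. VIM, an intermediate filament of mesenchymal cells (chromosome 10, 17228259 to 17237593), rose from 3.12 ± 1.79 to 71.7 ± 13.4 CPM (mean ± SD, n = 3 each). MMP14, a membrane-bound collagenase (chromosome 14, 22836557 to 22849027), rose from 1.25 ± 1.12 to 38.5 ± 9.87 CPM. SERPINE1, the main inhibitor of plasminogen activators (chromosome 7, 101127089 to 101139266), rose from 5.09 ± 4.81 to 99.96 ± 33.3 CPM. Their log2 fold changes were 4.52 ± 0.34 (SE) for VIM, 4.93 ± 0.46 for MMP14 and 4.29 ± 0.62 for SERPINE1. The adjusted p was 0.00111, 0.00167 and 0.00959 in that order.

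Across 19657 genes tested, edgeR's quasi-likelihood test called 568 at an adjusted p under 0.05, of which 560 were higher and 8 lower with collagen-tracks. Of the higher genes, 457 lay under 1 CPM on collagen, 294 of them under 0.1 CPM, and 16 at 10 CPM or more. Their median log2 fold change was 3.42, also with the 78 genes of at most 3 collagen counts set to the ratio to 3 counts over the group, and 499 were protein coding. The gain over all 560 genes summed to 1908 CPM. In all 568 called genes the groups did not overlap, as in 17.7% of all tested genes, where chance gives 10%. With the replicate block, 811 genes passed, 688 higher and 123 lower, and 562 were shared. The count rested in part on the collagen library numbered 4, without which 2448 genes passed, 1336 higher and 1112 lower. It was 227 with a filter at 1 CPM in 3 libraries, and 0 of 9340 with edgeR under a filter at 10 CPM on average, where 693 genes had an unadjusted p under 0.05. VIM and MMP14 kept log2 fold changes of 4.51 and 4.93 under that filter, but not their calls (adjusted p = 0.0521 for each).

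**Figure D1:**
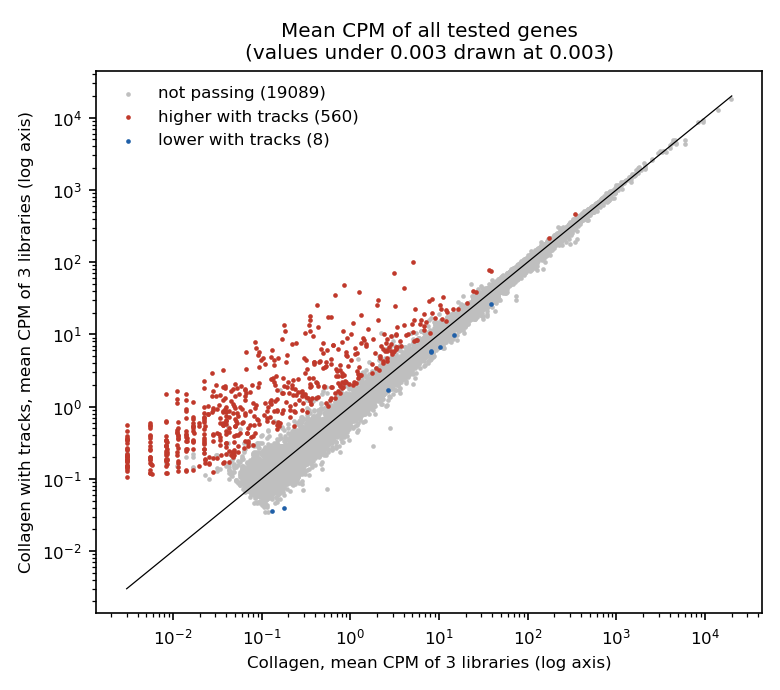
Mean CPM on collagen (x, log axis) against collagen with tracks (y, log axis) for the 19657 genes tested, each mean over 3 libraries, with the line of equal values. The 560 higher genes lie above the line, 457 of them at under 1 CPM on collagen, and the 8 lower genes lie below it, 6 of them with log2 fold changes of −0.63 to −0.48 and 2 with −2.15 and −1.95.

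The largest changes by the fixed rule, among called genes of at least 2 CPM, were in CAVIN3, DPYD, TNC, LAPTM5, CDH11, KIRREL1, IGFBP7, COL8A1, CST1, AXL, CTSZ and PLAU. CAVIN3, a caveolar coat protein, rose from 0.0278 ± 0.0482 to 2.91 ± 1.05 CPM (log2 fold change 6.59 ± 0.63, adjusted p = 0.00136). TNC, the matrix protein tenascin C, rose from 0.0838 ± 0.116 to 7.83 ± 1.73 CPM (6.50 ± 0.44, adjusted p = 8.48e-04). AXL, a receptor tyrosine kinase, rose from 0.422 ± 0.582 to 25.4 ± 4.37 CPM. PLAU, the urokinase plasminogen activator, rose from 0.849 ± 1.41 to 47.9 ± 11.96 CPM. Called with the smallest adjusted p were ETV1, PKIA, GALNT5, COL1A2 and ROBO4. ETV1, an ETS transcription factor, had 3 counts in the collagen group and 447 with tracks, a ratio of 172.5 with a 95% counting interval of 58.65 to 839.6 (adjusted p = 3.09e-05). Such intervals cover counting error only. CDH11 lost its call under DESeq2 (adjusted p = 0.0546). The sizes and order of these changes rested on the collagen library numbered 2, without which 27 of 65 called named genes moved by over 1.5 times in the fitted fold, each to a larger one. The log2 fold change was then 8.74 for TNC, 8.20 for AXL, 10.40 for PLAU, 6.004 for MMP14, 5.41 for SERPINE1 and 5.11 for VIM. The collagen libraries 1 and 4 held no count of CAVIN3, CDH11 or COL8A1, which against a floor of 3 counts over both libraries were at least 217-fold, 425.5-fold and 150.2-fold higher with tracks. KIRREL1 had 2 counts there (ratio 744, interval 206 to 6151).

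Of the list of markers high in basal mesenchymal breast lines such as MDA-MB-231 and low in MCF-7 cells, 21 of 22 rose, and none fell. The median log2 fold change was 3.61, and 22 passed when adjusted over the list alone. ANXA1, a phospholipid-binding protein, rose from 0.832 ± 0.301 to 11.2 ± 1.88 CPM, and CAV2, a caveolin, from 0.491 ± 0.147 to 5.51 ± 1.27 CPM. ZEB1, a repressor of epithelial genes, rose from 0.198 ± 0.0238 to 2.20 ± 0.499 CPM. The exception, IGFBP6, had a log2 fold change of 0.97 ± 0.27 (adjusted p = 0.176), and passed with the replicate block (adjusted p = 0.0415). On collagen alone, 9 of the markers reached 1 CPM and 1 reached 10 CPM. Of the 23 mesenchymal transition genes listed, 14 were tested. Of these, 8 rose, among them CDH11, TNC, VIM and ZEB1, and 10 passed over the list alone. Of those 8, 3 are also basal markers. Of the 12 fibroblast markers listed, only 5 were tested. COL1A2 and PDGFRB rose among them, and 3 passed over the list alone. COL1A2 had 5 counts on collagen and 366 with tracks. Camera gave adjusted p = 1.38e-70 for the basal markers, 3.26e-23 for the mesenchymal genes and 6.11e-08 for the fibroblast markers. All of these calls were lost with an estimated correlation (adjusted p = 0.103 for each).

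**Figure D2:**
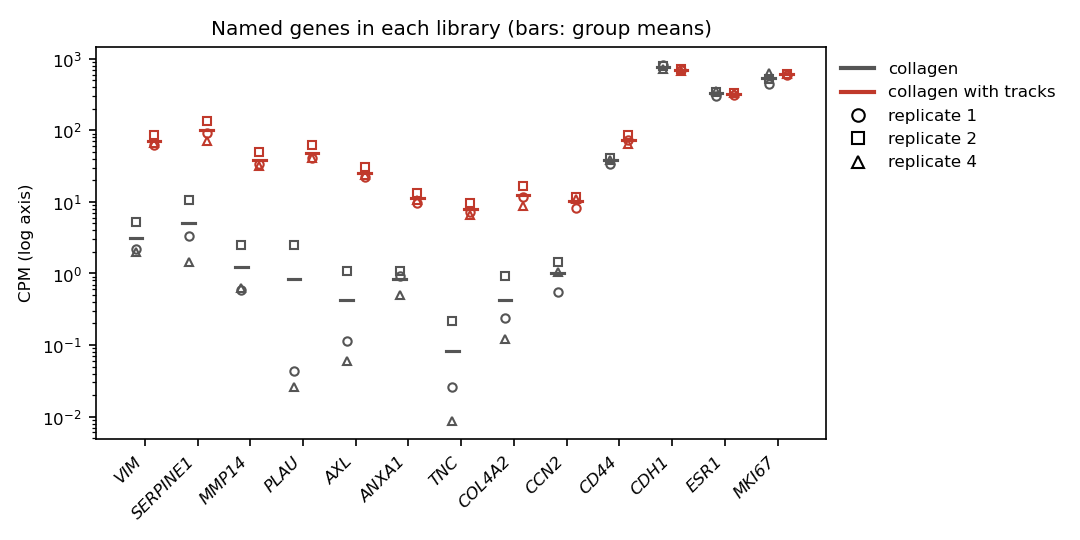
CPM (log axis) of 13 named genes in each of the 6 libraries; grey symbols are collagen, red symbols collagen with tracks, shapes give the replicate number, and bars are group means over 3 libraries. VIM to CD44 were called higher, while CDH1, ESR1 and MKI67 did not pass. The collagen library numbered 2 is the highest of its group for every gene from VIM to CD44.

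The levels of these markers also differed among the collagen libraries. PLAU stood at 0.0432, 2.48 and 0.0257 CPM in the collagen libraries numbered 1, 2 and 4, and at 40.5, 61.7 and 41.4 CPM in the libraries with tracks. AXL stood at 0.112, 1.09 and 0.0599 CPM on collagen and at 22.3, 30.4 and 23.5 CPM with tracks. Library 2 was thus the highest of both groups for both genes. Without the collagen library numbered 2, 21 basal markers and 8 mesenchymal genes passed, as with all libraries.

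Among matrix proteases and their inhibitors, 12 of 33 rose, none fell, and 14 passed over the list alone. With the filter at 1 CPM, 6 of 25 rose. Besides MMP14 they included PLAT, the tissue plasminogen activator, at 0.353 ± 0.418 and 11.03 ± 5.10 CPM. TIMP4 had 2 counts on collagen and 48 with tracks (ratio 27.8, interval 7.28 to 236), and ADAMTS1 had 1 and 159 (ratio 184, interval 32.6 to 7316). The collagen library 2 held none of these counts, and without it the ratios were 18.3 (4.81 to 155.7) and 121.5 (21.5 to 4827). Of the extracellular matrix genes, 11 of 30 rose, and 12 over the list alone. COL4A2, a basement membrane collagen chain, rose from 0.432 ± 0.439 to 12.5 ± 4.02 CPM, and LOX, which cross-links collagen, from 0.643 ± 0.117 to 7.14 ± 2.76 CPM. Of the 20 integrins and collagen receptors, 4 rose, ITGA6, ITGB3, CD44 and ITGA5, and 8 passed over the list alone. CD44, a hyaluronan receptor, rose from 38.1 ± 4.05 to 74.3 ± 10.6 CPM (log2 fold change 0.96 ± 0.12, adjusted p = 0.00501). ITGA2 and ITGB1, the subunits of a collagen receptor, had log2 fold changes of 0.25 ± 0.06 (adjusted p = 0.135) and 0.28 ± 0.09 (adjusted p = 0.287). DDR1, a collagen-binding kinase, had −0.10 ± 0.15 (adjusted p = 0.779). With the replicate block 7 of this list passed, ITGA2 (adjusted p = 0.0472) and ITGB1 (adjusted p = 0.0237) among them, and ITGA2 also passed under DESeq2 (0.0163). Of 25 invadopodia genes, MMP14 and SH3PXD2A, a scaffold of these protrusions, rose, and 4 passed over the list alone. CTTN had −0.12 ± 0.07 (adjusted p = 0.528).

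By camera the adjusted p was 1.49e-10 for the proteases, 2.13e-13 for the matrix genes, 1.51e-04 for the receptors and 0.0287 for the invadopodia genes. With an estimated correlation the adjusted p was 0.166, 0.194, 0.467 and 0.270. Median log2 fold changes, in that order, were 0.161, 0.32, 0.0098 and 0.038, under means of 1.38, 1.43, 0.385 and 0.376. Part of each list thus carried these calls. On collagen, 15 of the 33 proteases, 11 of 30 matrix genes, 10 of 20 receptors and 21 of 25 invadopodia genes reached 10 CPM. Camera did not match genes on level. Without the collagen library numbered 4, the receptors had adjusted p = 0.101 and the invadopodia genes 0.0507, with 6 receptors higher and 2 lower, and 5 invadopodia genes higher and 2 lower. In that setting 14 proteases were higher and 2 lower, and 11 matrix genes higher and 1 lower. Of the genes that rose, 3 proteases, 1 matrix gene and 1 receptor are also basal markers. The basal list holds only 22 genes. Here and below, such overlaps do not show that the other genes that rose form a separate signal.

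Of the targets of the transcriptional coactivators YAP and TAZ, 9 of 22 rose, and 11 over the list alone. CCN2, a matricellular protein, rose from 1.01 ± 0.438 to 10.2 ± 1.73 CPM (3.31 ± 0.27, adjusted p = 0.00127), and NT5E, an ectonucleotidase, from 0.608 ± 0.494 to 17.1 ± 4.50 CPM. Of the immediate early and ERK output genes, 5 of 26 rose, including FOSL1, DUSP6, ETV5 and EGR3, and 8 over the list alone. With the replicate block 8 passed. Without the collagen library 2 or the tracks library 2, 3 passed, and without the collagen library 4, 9 were higher and 1 lower. Of the TGF-beta targets, CCN2, TGFBI and SERPINE1 rose among 21, and 4 rose and 1 fell over the list alone. Camera gave adjusted p = 5.54e-16, 1.09e-05 and 0.157 for these 3 lists, and 0.103, 0.103 and 0.692 with an estimated correlation. Median log2 fold changes of the YAP and TAZ and the ERK lists were 0.46 and 0.181, under means of 1.52 and 0.55. Part of each of these lists thus carried its camera call. The TGF-beta list passed camera with the replicate block (adjusted p = 0.00105), where 5 members rose, and lost that call with an estimated correlation in the blocked fit (adjusted p = 0.332). DESeq2 gave 4 members higher and 1 lower, ID3 (adjusted p = 0.0329), named after its values were seen. In the fit without the collagen library 4, 4 TGF-beta targets were higher and 2 lower. The list's median log2 fold change, −0.04, had the opposite sign to its mean of 0.49. Among actin and Rho GTPase genes, MYL9 and MSN rose out of 33 (camera adjusted p = 0.157), with 3 higher and 2 lower without the collagen library 4. Of the genes that rose, 2 TGF-beta targets, 1 YAP and TAZ target, 1 ERK output gene and 1 actin gene are also basal markers. MSN, an actin-membrane linker, stood at 0, 2.002 and 0.0086 CPM in the collagen libraries, and lost its call under DESeq2 (adjusted p = 0.183) and the older edgeR form (0.0663). Of 22 hypoxia genes LOX rose (camera adjusted p = 0.0300), and of 18 NF-kappaB and cytokine genes CSF1 rose (0.0172). With an estimated correlation the adjusted p of these last lists was 0.467 and 0.685. The hypoxia call ended without the collagen library 4 (adjusted p = 0.238), the tracks library 1 (0.0526) or the tracks library 2 (0.0748), and with the replicate block 3 members rose, as did 2 without the collagen library 1, the collagen library 4 or the tracks library 4. That of the cytokine list ended with the replicate block (adjusted p = 0.0769), with the filter at 1 CPM (0.148), without the collagen library 4 (0.3002) and without the tracks library 2 (0.0527). Of this list 1 gene was higher and 1 lower with the replicate block, 2 higher and 3 lower without the collagen library 4, and 2 higher without the collagen library 1.

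None of 28 epithelial junction and identity genes and none of 20 luminal identity genes passed in edgeR's main test, over all genes or over the list alone. CDH1, the epithelial cadherin, stood at 775 ± 58.4 and 695 ± 13.2 CPM (log2 fold change −0.16 ± 0.07, adjusted p = 0.419). The estrogen receptor gene ESR1 stood at 333.5 ± 30.2 and 326 ± 11.95 CPM (−0.03 ± 0.08, adjusted p = 0.859). The tight junction gene CGN had −0.35 ± 0.08 (adjusted p = 0.110), and passed with the replicate block (adjusted p = 0.0476) and under DESeq2 (−0.336, adjusted p = 0.0153). JUP, also of the epithelial list, had −0.21 ± 0.06 (adjusted p = 0.225). MLPH, of the luminal list, had −0.27 ± 0.10 (adjusted p = 0.331). By camera the adjusted p was 0.0671 for the epithelial and 0.291 for the luminal list. With the replicate block camera gave 0.053 and 0.183. Log2 fold changes lay above 0 in 9 of 28 epithelial and 8 of 20 luminal genes. A modest fall of the epithelial list is thus not excluded. With the collagen library 4 left out, 4 epithelial genes were lower and 1 higher, and 2 luminal genes were lower. CDH1 then had an adjusted p of 0.0405, and JUP of 0.021. Of the estrogen receptor targets, IGFBP4 and EGR3 rose among 28 (log2 fold changes 0.42 ± 0.06 and 1.12 ± 0.18), and 3 passed over the list alone. Camera gave adjusted p = 0.00522 for that list, and 0.320 with an estimated correlation. The replicate block gave 9 higher targets. None passed without the collagen library 2 or without the tracks library 2, 1 without the tracks library 1, and 4 without the collagen library 4.

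No single gene passed among 25 mitotic genes, 25 DNA replication genes, 20 p53 targets or 28 interferon-stimulated genes, in the main test or over the list alone. Their median log2 fold changes were 0.19, 0.21, −0.26 and −0.31. MKI67, a marker of cycling cells, stood at 536.9 ± 99.2 and 604 ± 13.1 CPM (0.17 ± 0.12, adjusted p = 0.587). BTG2, a p53 target, had −0.78 ± 0.30 (adjusted p = 0.371). Camera gave adjusted p = 0.00257 for the mitotic and 0.00171 for the replication genes, upwards, and 0.00408 for the p53 targets, downwards. Each was 0.692 with an estimated correlation. Without the collagen library numbered 1 these camera calls ended (adjusted p = 0.134, 0.0960 and 0.159). Without the collagen library numbered 4, 14 mitotic and 16 replication genes were higher and 13 p53 targets lower. MX1, an interferon-induced GTPase, stood at 3.02 ± 1.39 and 8.15 ± 2.82 CPM (adjusted p = 0.131), and passed with the replicate block (adjusted p = 9.28e-04) and under DESeq2 (0.00138).

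The collagen libraries differed among themselves in these lists. Relative to the mean of all 6 libraries, the interferon-stimulated genes had median log2 levels of 1.22, 0.12 and −1.56 on collagen 1, 2 and 4, and of 0.59, 0.04 and −0.62 with tracks. The p53 targets had 0.49, 0.23 and −0.35 on collagen, and −0.02, −0.05 and −0.29 with tracks. For the mitotic genes the collagen library 1 lay farthest from that mean, with −0.35, −0.12 and 0.15 on collagen and 0.07, 0.06 and 0.17 with tracks. The replication genes likewise had −0.38, −0.13 and 0.15 on collagen, and 0.08, 0.08 and 0.16 with tracks.

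**Figure D3:**
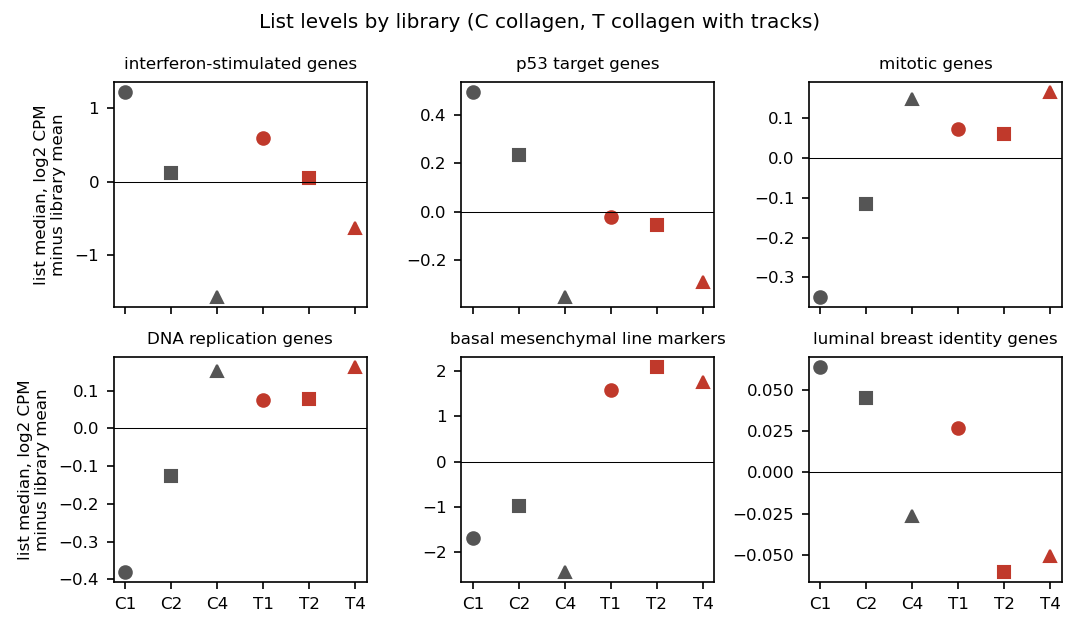
Median over each list of log2 CPM minus the mean of all 6 libraries (y, each panel with its own scale) for the collagen libraries 1, 2 and 4 (C, grey) and the libraries with tracks (T, red). The basal markers separate the groups, from −2.44 to −0.97 on collagen and from 1.57 to 2.08 with tracks, while the interferon-stimulated genes are lowest in the library numbered 4 of each group.

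The cytosolic ribosomal protein genes had a median log2 fold change of 0.12 over 40 genes (camera adjusted p = 0.00983), and the mitochondrially encoded genes of −0.11 over 13 (adjusted p = 0.0103). With an estimated correlation these were 0.802 and 0.160. The ribosomal call ended without the collagen library 1 (adjusted p = 0.571) or the tracks library 4 (0.189). Mitochondrial genes made up 8.14% to 8.96% of counts on collagen and 7.67% to 7.79% with tracks. No member of either list passed the main test, while MT-CO1, named after its values were seen, was lower with no filter on low counts (adjusted p = 0.0263), and 1 ribosomal gene was higher and 1 mitochondrial gene lower without the collagen library 4. Camera called none of the nuclear respiratory chain (adjusted p = 0.491), unfolded protein response (0.939), cholesterol synthesis (0.374), heat shock (0.368), extracellular vesicle (0.778) and microRNA processing lists (0.627), and no member passed the main test. DESeq2 called FDFT1 of the cholesterol list (adjusted p = 0.0335) and CD82 of the vesicle list (0.0195), both higher. With the collagen library 4 left out, 3 cholesterol genes were higher, and the other 5 of these lists had at most 2 genes in either direction. Of 33 genes of clathrin-mediated endocytosis, BIN1 rose (camera adjusted p = 0.939), 1 was higher and 1 lower without the collagen library 4, and its coat and adaptor genes CLTC and DAB2 had log2 fold changes of 0.00 ± 0.05 and −0.13 ± 0.19 (adjusted p = 0.974 and 0.760).

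Of genes reported as microRNA targets, none fell in any of the 6 lists in the main test. DESeq2 called 1 lower, the miR-221 and miR-222 target BMF (−0.579, adjusted p = 0.0243, against 0.190 in the main test), named after its values were seen. Of the reported miR-29 targets 6 of 22 rose (COL1A2, COL4A2, FBN1 and COL4A1 among them), of the miR-21 targets 4 of 21 (MARCKS, SATB1, YOD1 and TGFBR2), and of the let-7 targets 3 of 22 (IGF2BP3, HMGA2 and CDK6). Over the list alone, 7, 5 and 5 rose. Of the miR-29 targets that rose, 1 is also a basal marker. ITGB3 and ITGA5 rose among 15 miR-31 targets and CDKN1C among 18 targets of miR-221 and miR-222, with no member of the list for miR-10b, miR-100 and miR-125. PDCD4 and PTEN, textbook targets of miR-21, had log2 fold changes of 0.01 ± 0.08 (adjusted p = 0.953) and 0.08 ± 0.05 (adjusted p = 0.572). Camera gave adjusted p = 3.13e-07 for the miR-29, 3.69e-04 for the miR-21 and 1.16e-05 for the let-7 list, all upwards, and 0.103, 0.160 and 0.160 with an estimated correlation. For the other 3 lists it gave 0.108, 0.939 and 0.939. At 10 CPM or more on collagen, 7 of 12 miR-21 and 5 of 11 miR-29 targets lay below 0. Their median log2 fold changes were −0.038 and 0.031, so neither list moved one way at that level. Of the let-7 targets, 3 of 15 lay below 0 there. With the collagen library 4 left out, 6 let-7 targets were higher, and the lower genes were 3 targets of miR-221 and miR-222, 2 of miR-10b, miR-100 and miR-125, 1 of miR-21 and 1 of miR-29. CDK6 lost its call without the collagen library 2 (adjusted p = 0.118), the tracks library 1 (0.0655) or the tracks library 2 (0.0675).

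**Figure D4:**
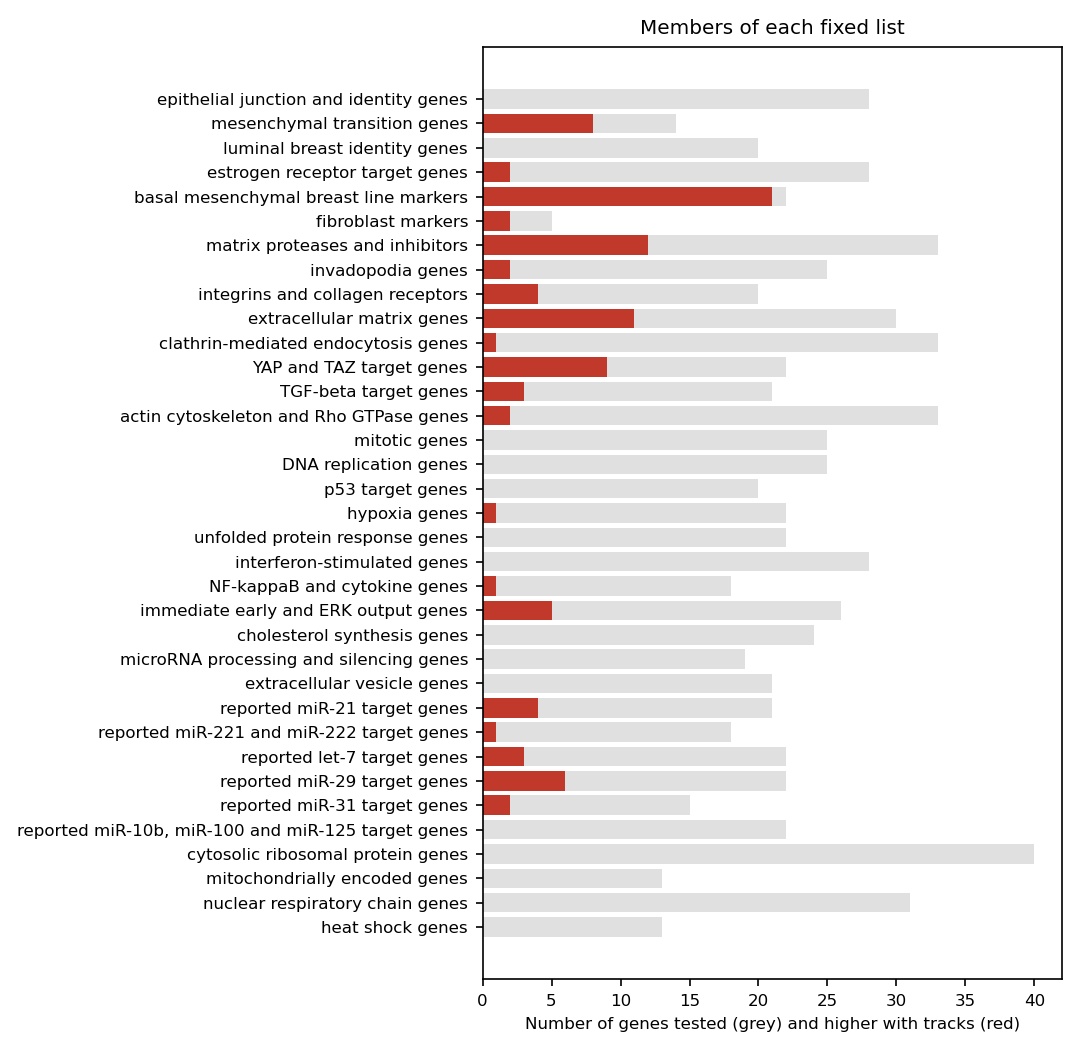
Number of genes tested (grey bars) and called higher with tracks (red) in each of the 35 gene lists; no member of any list was called lower by edgeR's main test. The basal mesenchymal markers had 21 of 22 higher, the proteases 12 of 33 and the epithelial and luminal lists none.

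The main test called 8 genes lower, and the replicate block 123, which are not listed here. Of the 8, those with the largest falls had no symbol, are annotated as transcribed pseudogenes and lay under 1 CPM. ENSG00000264057 fell from 0.179 ± 0.01998 to 0.0388 ± 0.0037 CPM (log2 fold change −2.15 ± 0.30, adjusted p = 0.00555), with 63 and 12 counts. ENSG00000205794 fell from 0.131 ± 0.0237 to 0.0356 ± 0.0131 CPM (−1.95 ± 0.37, adjusted p = 0.0242), with 46 and 10 counts. SNX25, a sorting nexin (chromosome 4, 185204237 to 185370185), fell from 38.2 ± 3.04 to 26.6 ± 2.98 CPM (log2 fold change −0.53 ± 0.10, adjusted p = 0.0362). PPFIBP2, a liprin, fell from 14.6 ± 1.97 to 9.85 ± 0.574 CPM (−0.57 ± 0.11, adjusted p = 0.0443). LINC00304, FAM110B and YJEFN3 had log2 fold changes of −0.63, −0.48 and −0.48. ENSG00000285796, annotated as antisense and also without a symbol, had −0.61. Tested genes overlap LINC00304 and YJEFN3 on the same strand, and SNX25, PPFIBP2, ENSG00000205794 and ENSG00000285796 on the other, so their counts are uncertain. Each of the 8 lost its call without at least 1 library. ENSG00000205794 also lost it with the replicate block (adjusted p = 0.0634). Without the tracks library 2, for example, SNX25 had an adjusted p of 0.0592, PPFIBP2 0.215, FAM110B 0.126 and YJEFN3 0.128.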

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

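Every alternative was planned before the data were examined. The count of 568 changed genes stayed within 1.5 times with DESeq2's size factors (585), library totals (557), no filter (613), DESeq2 (826, 710 higher and 116 lower, with 537 shared), limma-voom (550), the older edgeR form (534), a tested fold of 1.5 (450) and the replicate block (811). A filter at 1 CPM in 3 libraries left 227 genes among fewer tested. One at 10 CPM on average left 0 of 9340 with edgeR, where 693 had an unadjusted p under 0.05; no other tool was run with that filter. The cause was not tested beyond the smaller set of genes. Leaving out 1 library, or both of a number, gave 226 to 2448 genes, the highest without the collagen library 4 and the lowest without both libraries numbered 1, where 27 of the named called genes lost the call, SERPINE1 (adjusted p = 0.121) and PLAU (0.0588) among them. With the replicate block and a number left out, the counts were 1472 without number 1, 580 without number 2 and 4253 without number 4. The cause was not tested.

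Of 35 lists, 20 passed camera, 18 to 22 without a library, 19 with the 1 CPM filter, 20 with the replicate block (19 shared) and 0 with an estimated correlation, where fry called 13. The fibroblast list turned downwards under the 1 CPM filter (adjusted p = 0.693), which left fewer of its genes. Of the values of called genes under the alternatives, 1215 kept the call and 152 lost it, none with a change of direction. Some list counts also moved by over 1.5 times. With DESeq2, 4 invadopodia genes, 7 receptors, 8 ERK output genes and 5 let-7 targets were higher. The 1 CPM filter left 3 of 18 miR-29 targets, and a tested fold of 1.5 left 3 ERK output genes and 0 estrogen receptor targets. With the replicate block and number 4 left out, 20 interferon-stimulated genes and 16 p53 targets were lower, and 19 mitotic and 22 replication genes higher. Apart from the calls printed beside their results, the replicate block changed no other call of a gene or list named in the text.

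Genes with no call and a log2 fold change near 0 changed sign. With a library or a number left out, the log2 fold change ranged from −0.0912 to 0.0234 for ESR1, from −0.223 to 0.0974 for DDR1, from −0.273 to 0.1197 for DAB2, from −0.427 to 0.0265 for STAT2 and from −0.0515 to 0.0761 for PDCD4. With the replicate block and number 4 left out, ESR1 had 0.0222 and PDCD4 −0.0168. With number 1 left out, DDR1 had 0.0984 and DAB2 0.121. With library totals PDCD4 had −0.0021 and CLTC −0.0066, and with the 10 CPM filter CLTC had −0.0025. Depth limits the 294 higher genes under 0.1 CPM on collagen, whose fold changes rest on few counts.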

Other observations

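All tests below were chosen after the results were seen, and only the gene lists were fixed in advance. Gene families were formed by a shared symbol stem, 322 of them with at least 8 tested members. The collagens and the ADAMTS proteases held more higher genes than the share over all tested genes gives. Of 33 collagen genes 9 rose, where 0.94 were expected (one-sided Fisher's exact test, adjusted p = 7.82e-05), among them COL6A3, COL7A1, COL8A1, COL13A1, COL6A1 and COL6A2. Of 15 ADAMTS genes 5 rose, where 0.427 were expected (adjusted p = 0.00703), namely ADAMTS1, ADAMTS12, ADAMTS14, ADAMTS15 and ADAMTS16. The share of genes called higher depended on level, at 33.5% under 0.1 CPM on collagen and 0.2% at 10 to 100 CPM. The test neither matched genes on level nor allowed for genes that move together. It thus cannot tell a trait of a family from a low level on collagen. Of the genes at 10 CPM or more on collagen, named here after their values were seen, CCN1 rose from 11.01 ± 2.04 to 32.9 ± 5.13 CPM, PODXL from 36.7 to 77.0 CPM and MYO10 from 10.3 to 25.2 CPM.

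The libraries numbered 4 were low in interferon-stimulated genes in both groups, with all 28 members below the mean of the group's other libraries. Among genes picked after their values were seen, IFI6 stood at 298.6, 73.5 and 11.3 CPM on collagen 1, 2 and 4 and at 139, 74.0 and 23.1 CPM with tracks. MT2A, a metallothionein, went the other way, with 17.2 CPM in collagen library 4 against 3.18 and 3.90 CPM, and SLC30A1, a zinc exporter, stood at 55.4 against 13.4 and 14.5 CPM. MALAT1, a nuclear RNA, stood at 446, 391 and 198 CPM on collagen and at 197, 217 and 160 CPM with tracks. Between the groups, MALAT1 had an adjusted p of 0.278 and SLC30A1 of 0.698, and with the replicate block 0.0451 and 0.00895. Library depth is argued against, since collagen libraries 4 and 2 had totals in a ratio of 1.001 and differed by −1.50 in the median log2 level of the interferon list. Culture or handling shared by same-numbered libraries may account for it: the deviations of both libraries numbered 4 correlated across 9342 genes with r = 0.855, and with 0.833 without the interferon list. Genes are not independent, the labels give no batch, and no biological explanation was tested.

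Most higher genes moved together between tracks libraries 1 and 2. In the 298 whose level on collagen lay under 10% of that with tracks, the median log2 ratio of tracks library 2 to tracks library 1 was 0.572. Its 95% bootstrap interval over genes, 0.539 to 0.601, leaves out the spread between libraries. In 293 uncalled genes matched on level the median was −0.002, while the ratio lay above 0 in 285 of the 298. This was no trait of these genes alone: in gains over collagen, the log2 ratio of both libraries was 0.5002 in the other 262 higher genes, 237 of them above 0 in level, and 0.340 in the 16 at 10 CPM or more on collagen, 12 of them above 0 in level. The 22 basal markers of the fixed list had a ratio of gains of 0.601 with an SD of 0.119, and the most abundant in the libraries with tracks were SERPINE1 (99.96 CPM), CD44 (74.3), VIM (71.7) and PLAU (47.9). For tracks library 4 over library 1, the median log2 ratio in the 298 genes was −0.136, with 117 above 0. In the matched genes it was −0.019. Over 112 of the 298, at 1 CPM or more with tracks, that ratio had an SD of 0.313. For libraries 2 and 1 the SD was 0.167, so the common ratio was seen mainly between these libraries. A candidate explanation is RNA from other cells of a basal mesenchymal type, carried with the tracks, though a shared programme in MCF-7 cells would give such a common ratio too. A response of the MCF-7 cells cannot be told apart from it, because no sample held tracks without MCF-7 cells. At 10 to 100 CPM on collagen 4 of 7036 genes rose at least 2-fold, and at 100 CPM or more 0 of 2300. Dilution by other RNA is argued against for the 8 lower genes, whose smallest fall needs a share of 28.2%, where the bootstrap interval of the luminal list allows 8.70%. That interval is over 20 genes, leaves out the spread between libraries and uses TMM-scaled values. It compares the falls with those of luminal genes and does not bound the share of other RNA itself.

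Collagen library 2 held a small part of the same gain. Over 112 of these genes at 1 CPM or more with tracks, a median of 5.77% of the gain was found there (quartiles 3.67% and 7.14%), and 110 of the genes lay above the mean of collagen libraries 1 and 4. These genes were chosen for a collagen mean under 10% of the tracks level. Collagen library 2 entered that mean, so the choice itself kept its share small. The counts of collagen library 2 were closest to the profile of tracks library 2 (deviance 522, against 592 for library 1 and 924 for library 4). Reads or RNA from a collagen-tracks library, or a small amount of the same other cells, may each give this, and the counts cannot be told apart by source, since both explanations predict a common share.

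The hypothesis that microRNAs of the tracks lower their reported targets was not decided. Over 75 reported target genes at 10 CPM or more, the median log2 fold change was 0.00792 (95% bootstrap interval over genes −0.042 to 0.043), against 0.0085 in all genes at that level, and 36 of them lay below 0. The interval leaves out the spread between libraries, and a median over genes that go both ways excludes no fall for a single microRNA. At that level the 13 targets of miR-221 and miR-222 had a median of −0.076 (−0.324 to −0.016) and the 15 let-7 targets one of 0.057 (0.0079 to 0.09999), not adjusted over the 6 lists. Over all 18 targets of miR-221 and miR-222 the interval, −0.287 to 0.0088, included 0. No single one was called lower by edgeR's main test, and DESeq2 called 1. Targets outside these lists were not examined.

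The real grouping gave 568 changed genes, and the highest of the other 9 ways to split the 6 libraries gave 0. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The other splits that part all 3 pairs also gave 0.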
